A study of Chelonus formosanus with 6 samples.

How the data were processed

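The series measured RNA of heads of the wasp Chelonus formosanus by paired-end sequencing of poly(A) libraries, 3 from females and 3 from males. Per the labels' protocols, RNA was extracted with Trizol, libraries were sequenced on an Illumina NovaSeq, reads were cleaned with Cutadapt and in-house Perl scripts and checked with FastQC, and the transcriptome was assembled de novo with Trinity 2.4.0, the longest transcript of each cluster being taken as the unigene. An assembly without a genome can split a gene into several unigenes, merge close copies, and keep transcripts of other organisms in the material. The read counter, the annotation steps and the authors' test are not given in the sources used here, and no reference genome was used.

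The deposited table holds expected counts, which per the file headers the authors estimated for each unigene and library from the reads and did not normalize; between 8.81% and 9.5% of the values in each library are not whole, and they were rounded before testing. It also holds TPM per library and mean TPM per sex, per the file headers, which the authors computed within each library and which were used here for description only. The authors' deposited log2 fold change (female over male), p-value and FDR were used only to set their calls beside those made here. Some annotation cells, 1175 of gene ontology and 500 of orthologous groups, carried a placeholder in place of text and were treated as empty. All sample columns matched a sample by name (0 did not). Groups were taken from the sex given in the labels.

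Counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood test of female minus male), with Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3. Of 41986 unigenes 21196 passed the filter. CPM values are counts scaled by library total and TMM factor. Total counts ran from 17937390 to 19517887 per library, and the biological coefficient of variation was 14.49%. Intervals from counts are exact binomial at 95% and cover counting error only. Gene lists, 34 in all, were fixed before the data were examined as word patterns searched in the unigene descriptions, so a list holds what its words match; 2 had fewer than 5 tested members. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 and, beside it, with an estimated correlation. The estimated setting also takes its p from the few residual degrees of freedom of the libraries. A call lost there is thus not by itself a sign of correlated members. Lists were also tested with fry, which asks whether the members move on balance in a direction without comparing them with other genes. Annotation terms with 10 to 500 tested unigenes were tested with Fisher's exact test, one-sided for excess, against the tested unigenes with a term of that kind. Reference families were described by the coefficient of variation, the geNorm M and the percentile of the log2 standard deviation among the 500 unigenes nearest in mean level. Shares of counts by the species of the best hit were compared with an exact two-sided permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, permutations and plots.

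The unigenes named in the text were set by a rule fixed before the data were examined. It took the 8 with the largest difference in each direction among those past the threshold with a mean of at least 50 counts in the higher sex, no overlap between the sexes and an informative description; in each list the 2 with the smallest p in each direction, or the smallest p where none passed; the highest-mean member of each reference family; and the 3 with the smallest p. Unigenes named outside that rule are marked as chosen after their values were seen, or stand in the closing part.

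The steps were tested on simulated counts for 20431 unigenes drawn with the means, dispersions and library sizes of these samples. For the comparison of female with male heads, edgeR recovered 56.7% of 97 unigenes changed by 1 on the log2 scale and 92.9% of 98 changed by 2, none in the wrong direction, with 16 false calls (9.3% of its calls, above the nominal 5%). DESeq2 1.42.0 recovered 58.8% and 88.8%, with 27 false calls (14.8%). The planted list of 50 unigenes was called and 0 of 30 unchanged lists were. Unigenes were drawn independently in this simulation, so it could not show how often lists of correlated members are called falsely.

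Alternatives fixed before the data were examined were a replicate block, leaving out each library in turn, DESeq2 size factors, DESeq2's Wald test, no filter and a stricter filter on low counts, summing unigenes of a description, a log2 difference of at least 1, an estimated correlation, the second-highest member of each reference family, and 1 unigene per description for terms. The alternatives for tables without counts did not apply. A test without vertebrate hits (for lists also with an estimated correlation) and a scaling to the total of hymenopteran counts were chosen after seeing the data.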

Results

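The series followed Chelonus formosanus, a braconid wasp that lays its eggs in the eggs of moths and develops in the larvae. Poly(A) RNA of heads was sequenced from 3 female and 3 male libraries, all given day 1 in the labels. With no genome used here, reads had been assembled into 41986 unigenes, clusters of transcripts that stand for genes, of which 24306 (57.9%) had a protein database hit. Total counts per library were 18053471, 18952196 and 19517887 for females 1 to 3 and 18528160, 17937390 and 19338480 for males 1 to 3. Between 96.4% and 97.9% of the unigenes had a count above 0 in each library. The labels do not say whether libraries came from separate animals or pools, so the p-values measure the spread between these samples, which may be technical. The stated purpose was to choose reference genes for quantitative PCR from these transcriptomes, and the libraries compare the sexes. The quantitative PCR of other tissues, temperatures and insecticides is not analysed here.

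Female and male heads differed in 593 of the 21196 unigenes tested (2.8%; edgeR's quasi-likelihood test, adjusted p under 0.05), with 358 higher in females and 235 higher in males. A cytochrome P450 4C1-like unigene (TRINITY_DN24822_c1_g4), of a family of oxidising enzymes, stood at 220.1 ± 22.1 CPM in females and 1.86 ± 0.155 CPM in males (mean ± SD, n = 3 libraries per sex, as for every pair of values here), a 118-fold difference by edgeR (adjusted p = 7.03e-10). Higher in males were an acyl-CoA synthetase short-chain family member 3 unigene, an enzyme that activates short fatty acids (TRINITY_DN25933_c1_g3; 2.55 ± 3.3 against 110.6 ± 19.2 CPM, 44.4-fold, adjusted p = 0.000293), and a unigene named venom protein Ci-23b (TRINITY_DN25103_c1_g3; 1.49 ± 2.01 against 61.1 ± 11.4 CPM, 41.9-fold, adjusted p = 0.000283). In both of these unigenes female 1, at 6.35 and 3.81 CPM, lay above the other females. Without female 1 the log2 differences moved from -5.47 to -7.41 and from -5.39 to -7.48. A nose resistant to fluoxetine protein 6-like unigene was 11.1-fold higher in males, Lipase 1, of the triacylglycerol lipases, 9.55-fold, a solute carrier family 26 member 10-like unigene 7.11-fold, and a phytanoyl-CoA dioxygenase, an enzyme of peroxisomal fatty acid breakdown, 6.55-fold. A pair of unigenes without a description, TRINITY_DN26069_c0_g3 and TRINITY_DN4114_c0_g1, were 138-fold and 253-fold higher in females (adjusted p = 7.03e-10 and 2.14e-09). The median absolute log2 difference of the 593 unigenes was 0.91 (1.88-fold), and 271 of them, 164 higher in females and 107 in males, differed by at least 1 on the log2 scale. An unadjusted p under 0.05 was found for 2543 unigenes, where 1060 would be expected by chance, and 3659 (17.3%) had no overlap between the sexes, where chance gives 10%. Without female 2 the count was 358 and without male 2 it was 357. DESeq2's Wald test called 817, with 458 higher in females and 359 in males. The authors' deposited test had 355 significant unigenes, 223 higher in females and 132 higher in males, and 259 of these were among the 593, all in the same direction. The authors' FDR was under 0.05 for 793 unigenes, more than the 355, and for 568 of the 593.

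Odorant receptors, the membrane proteins with which antennal neurons detect volatile compounds, were the gene group with the most calls. Of 104 receptor unigenes tested, 38 were higher in females, 5 were higher in males and 61 did not pass the test (50 and 7 adjusted over the list alone). The odorant receptor coreceptor Orco, with which these receptors form channels, stood at 370.1 ± 32.2 CPM in females and 158 ± 0.31 CPM in males (2.35-fold, adjusted p = 1.06e-05; TRINITY_DN25907_c2_g3, chosen after its values were seen). An odorant receptor 13a-like unigene (TRINITY_DN26448_c0_g5) had 1636 counts in the 3 female libraries and 7 in the 3 male libraries, a ratio of 224 with a 95% counting interval of 109 to 558. Odorant receptor 67a-like was 25.2-fold, 22c-like 12.4-fold, 13a (TRINITY_DN25784_c0_g5) 8.44-fold, olfactory receptor 58 7.67-fold and the odorant receptor TRINITY_DN970_c0_g1 7.21-fold higher in females. The log2 difference of the last was 2.85, and 3.47 without male 1. Olfactory receptor 9 had 153 counts in females and 6 in males, a ratio of 24.5 (11 to 67.7). In the other direction, odorant receptor 46a-like was 4.74-fold and odorant receptor 35 2.97-fold higher in males. The list's median log2 difference was 0.56 (adjusted camera p = 6.03e-20 with the preset correlation; adjusted p = 0.157 with an estimated correlation), and fry gave an adjusted p of 0.00576. Receptors of this family share sequence, so reads may have been split between near-identical copies, and the folds of single receptor unigenes are uncertain to that extent.

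**Figure D1:**
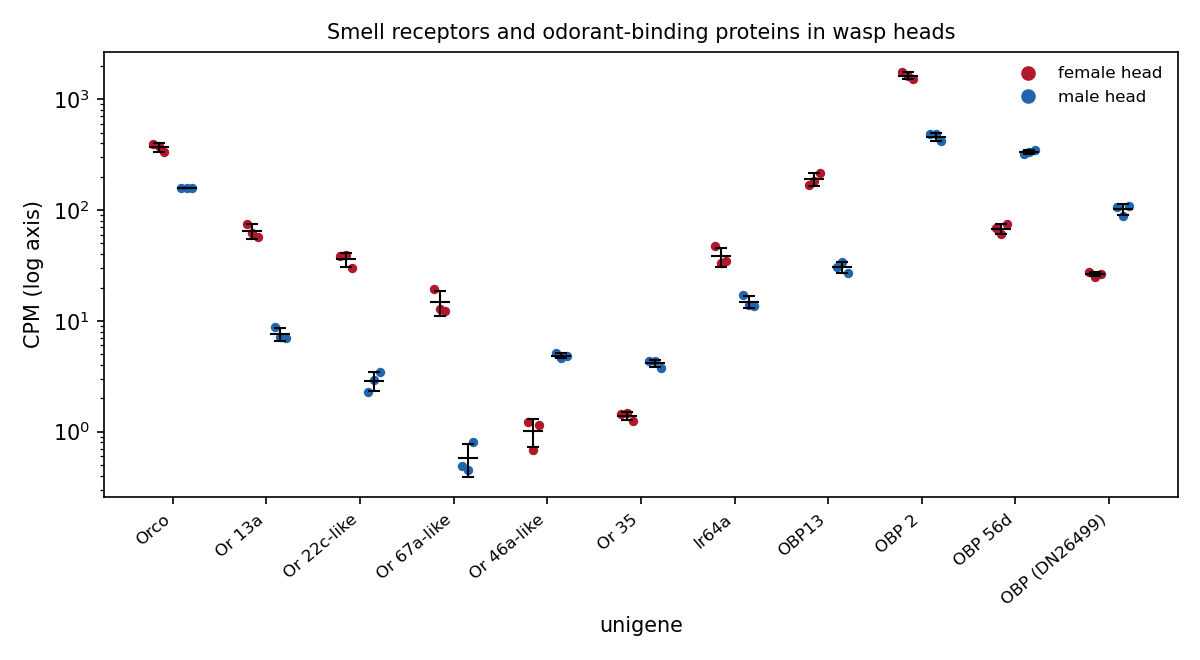
Expression in CPM (log axis) of 7 receptor unigenes and 4 odorant-binding protein unigenes in each library, with points for the 3 female and 3 male head libraries and bars for the mean and SD. Orco stands at 370.1 CPM in females and 158 CPM in males, whereas odorant-binding protein 56d stands at 68.1 and 336.1 CPM.

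Odorant-binding proteins, small secreted proteins that carry odorants to the receptors, differed in both directions. Of 18 tested, 4 were higher in females, 5 were higher in males and 9 did not pass (7 and 5 adjusted over the list alone). OBP13 stood at 189 ± 25.9 CPM in females and 30.5 ± 3.44 in males (6.21-fold, adjusted p = 5.53e-07), and odorant binding protein 2 at 1641 ± 124 and 461 ± 38.3 CPM (3.56-fold). General odorant-binding protein 56d (TRINITY_DN25379_c2_g1) stood at 68.1 ± 7.24 CPM in females and 336.1 ± 14.2 in males (4.93-fold, adjusted p = 2.46e-07), and the odorant-binding protein TRINITY_DN26499_c1_g12 was 3.85-fold higher in males. The list as a whole did not pass the camera test (median log2 -0.14, adjusted p = 0.92). Leaving out a library moved the list's median from -0.515 (without male 2) to 0.106 (without male 1), so its sign is not settled. Of its members 5 had their best hit in a vertebrate, without which the median was 0.24. Among these 5, odorant-binding proteins 1a and 1b were at 50.4 and 52.9 CPM in male 2 against 157 and 199 CPM in male 1. The shift without male 2 may thus come in part from vertebrate hits. Both ionotropic receptor unigenes tested, members of a second family of sensory channels, were higher in females (ionotropic receptor 64a 2.57-fold, adjusted p = 0.00053, and TRINITY_DN17960_c0_g1 2.11-fold, adjusted p = 0.000621), and this list was too small for a list test. Among 11 gustatory receptors, which detect tastants, 2 were higher in females and 1 in males, the same counts as adjusted over the list alone (camera adjusted p = 0.482). They were gustatory receptor 28a (2.03-fold, lost in 4 of 13 alternative settings), gustatory receptor 6 (1.57-fold, lost in 3) and TRINITY_DN26283_c0_g7, 2.77-fold higher in males. None of the 5 chemosensory proteins passed edgeR's test, over all unigenes or adjusted over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2); their camera adjusted p was 0.213, and 0.0352 without female 1 (with all libraries, adjusted p = 0.666 with an estimated correlation). Their smallest p belonged to the odorant-binding protein A10 unigene, at 10.4 ± 2.61 and 6.98 ± 0.715 CPM (adjusted p = 0.233).

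Genes of vision and of detoxification held single large differences. Of 38 phototransduction unigenes, 2 were higher in females and 1 in males (3 and 1 adjusted over the list alone). The ultraviolet-sensitive opsin, a light receptor, was at 554 ± 47.5 CPM in females and 407 ± 25.5 in males (1.36-fold, adjusted p = 0.0213, lost in 4 of 13 settings). Retinol dehydrogenase 14, named for an enzyme of retinoid turnover, was 2.37-fold higher in females in the unigene TRINITY_DN26289_c1_g1 and 16.0-fold higher in males in TRINITY_DN26289_c2_g8. The phototransduction list had a camera adjusted p of 0.0809, which fell to 0.0352 without female 1, 0.0387 without female 2 and 0.0223 with no filter on low counts (with all libraries and the filter, adjusted p = 0.666 with an estimated correlation). Of 63 cytochrome P450 unigenes, 5 were higher in females and 2 in males (8 and 3 adjusted over the list alone), among them P450 6k1 (1715 ± 66.9 and 965 ± 102 CPM, 1.78-fold higher in females) and P450 304a1 (1.86-fold higher in males). The list had a camera adjusted p of 0.247. Of these 63, 30 had a best hit in a vertebrate; over the other 33 unigenes 6 were higher in females and 1 in males, and the camera adjusted p was 0.000305 (adjusted p = 0.217 with an estimated correlation). Other detoxification enzymes, which conjugate or export foreign compounds, had 9 of 65 higher in females and 4 in males (10 and 5 adjusted over the list alone). Examples were the glutathione S-transferase TRINITY_DN26448_c0_g1 (3.24-fold) and glutathione S-transferase 1-1 (2.2-fold) higher in females, and UDP-glucuronosyltransferase 2B15 (1.44-fold) and venom carboxylesterase-6 (1.85-fold) higher in males. The median of this list was -0.02 while its mean was 0.08 and the camera test pointed up (adjusted p = 0.313; 0.0367 without vertebrate hits, and there adjusted p = 0.38 with an estimated correlation).

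Some fatty acid and hydrocarbon synthesis genes, which make lipids that include those of the cuticle surface, were higher in female heads, and the list was called higher by camera with the preset correlation and by fry, not with an estimated correlation. Of 46 tested, 7 were higher in females and 1 in males (12 and 2 adjusted over the list alone; camera adjusted p = 0.000461; adjusted p = 0.316 with an estimated correlation). An acyl-CoA Delta(11) desaturase, which places a double bond in fatty acids, stood at 192 ± 6.36 and 115 ± 1.83 CPM (1.67-fold, adjusted p = 0.000141). The fatty acyl-CoA reductase CG5065 (TRINITY_DN479_c0_g2), which makes fatty alcohols, was 1.98-fold higher in females, and an acyl-CoA Delta(11) desaturase-like unigene was 1.64-fold higher in males. Of 58 cuticle and chitin proteins, 2 were higher in females and none in males by edgeR (4 and 3 adjusted over the list alone; camera adjusted p = 0.475). They were chitinase 3 (2.29-fold, lost in 4 of 13 settings), an enzyme that degrades chitin, and the endocuticle glycoprotein SgAbd-2 (1.38-fold, lost in 2).

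Reproductive and hormonal genes gave smaller sets of calls. Of 9 yolk and ovary unigenes, 2 were higher in females (4 adjusted over the list alone), both vitellogenin-2-like, named for the egg yolk precursor, at 8.09 ± 0.183 against 2.84 ± 0.5 CPM (2.85-fold) and 9.4 ± 1.29 against 4.22 ± 0.577 CPM (2.23-fold). The abundant vitellogenin-1-like unigene TRINITY_DN25214_c1_g3 had means of 2931 CPM in females and 2892 CPM in males (adjusted p = 0.977; chosen after its values were seen). The yolk list was higher in females (median log2 0.70, camera adjusted p = 0.00214; adjusted p = 0.197 with an estimated correlation), a call lost without male 1 (adjusted p = 0.0694). Leaving out a library gave list medians from 0.405 (without male 2) to 0.817 (without female 3). Krueppel homolog 1, a transcription factor induced by juvenile hormone, was 2.37-fold higher in females, and takeout, of a family of hormone-binding proteins, 1.51-fold. These were the 2 of 19 juvenile hormone and ecdysone unigenes past the test (3 and 1 adjusted over the list alone; camera adjusted p = 0.597). Major royal jelly protein 3 (1.85-fold) and a yellow-like unigene (1.94-fold) were higher in females, 2 of 8 in the yellow and royal jelly family (2 and 1 adjusted over the list alone; camera adjusted p = 0.313). None of 10 sex determination unigenes passed edgeR's test (3 at an unadjusted p under 0.05, 1 by DESeq2; 1 and 1 adjusted over the list alone; camera adjusted p = 0.207); the smallest p was that of a sex-lethal homolog, with 76.9 ± 7.35 CPM in females and 99 ± 11.6 in males (adjusted p = 0.122). Of 21 venom and bracovirus unigenes, Ci-23b and venom carboxylesterase-6 were higher in males (3 adjusted over the list alone), with a list median of 0.01, a mean of -0.18 and a camera adjusted p of 0.686. Of 36 unigenes with testis or sperm in their name or function, 2 passed the test, both before and adjusted over the list alone. Both were spermine oxidase-like, 2.05-fold and 1.33-fold higher in males, the latter a call lost in 8 of 13 settings. These enzymes break down polyamines and are not sperm proteins. That list had a camera adjusted p of 0.951.

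Some genes of the ciliary axoneme and of intraflagellar transport, which build cilia, were higher in female heads, and the list was called higher by camera with the preset correlation and by fry, not with an estimated correlation. Of 47 tested, 5 were higher in females and 1 in males (8 and 1 adjusted over the list alone; median log2 0.23, camera adjusted p = 0.000461; adjusted p = 0.157 with an estimated correlation). Intraflagellar transport protein 52 stood at 149 ± 14.8 CPM in females and 52.02 ± 5.21 in males (2.86-fold, adjusted p = 9.67e-06). Cilia- and flagella-associated protein 36 was 1.59-fold higher in females (lost in 1 of 13 settings), and the Axonemal 84 kDa protein 1.81-fold higher in males (lost in 5). Transposon and retroelement unigenes were also higher in females as a list (median log2 0.12, camera adjusted p = 0.00494; adjusted p = 0.157 with an estimated correlation), though 3 of 90 passed in that direction and 1 in males, as did the same numbers adjusted over the list alone. The reverse transcriptase TRINITY_DN25205_c0_g9 was 2.72-fold higher in females the transposon Ty3-G Gag-Pol polyprotein 2.01-fold, and the reverse transcriptase TRINITY_DN26556_c0_g6 was 3.07-fold higher in males.

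Some muscle and actin unigenes, of the contractile apparatus and the cytoskeleton, were lower in female heads. Both lists were called lower with camera's preset correlation, and neither passed with an estimated correlation or by fry. Of 62 muscle unigenes, 6 were lower in females and none higher by edgeR (14 and 1 adjusted over the list alone). Myosin regulatory light chain 2, a subunit of the contractile motor, stood at 3052 ± 454 CPM in females and 5622 ± 426 in males (1.84-fold, adjusted p = 0.00194), and tropomyosin-1, which lies along the thin filament, at 600.2 ± 89.7 and 1078 ± 50.7 CPM (1.8-fold, adjusted p = 0.00152). The muscle list was lower in females (median log2 -0.05, camera adjusted p = 0.00214; adjusted p = 0.666 with an estimated correlation; fry adjusted p = 0.377), a call lost without female 3 (adjusted p = 0.237). Scaling to hymenopteran counts turned its median to 0.01, and no filter on low counts to 0.02, while the test still pointed down. Of 13 actin unigenes, 3 were lower in females, the same number as adjusted over the list alone (camera adjusted p = 0.00318; adjusted p = 0.308 with an estimated correlation; fry adjusted p = 0.0639), with Actin (TRINITY_DN25761_c0_g5) at 1256 ± 281 and 2592 ± 121 CPM and actin, clone 205-like, at 715 ± 150 and 1514 ± 172 CPM. Of 14 fat body and haemolymph unigenes, apolipophorins, the lipid carrier of insect blood, was lower in females (3737 ± 358 and 5076 ± 367 CPM, 1.36-fold; 1 adjusted over the list alone), a call lost in 9 of 13 settings. That list passed narrowly (camera adjusted p = 0.0467; adjusted p = 0.308 with an estimated correlation) and was lost in 9 of 13 settings, with adjusted p reaching 0.24 without vertebrate hits; with no filter on low counts its median was 0.11.

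Peptide and neuronal signalling genes held few calls. Of 27 neuropeptides and peptide hormones, 2 were lower in females (1 higher and 4 lower adjusted over the list alone), the SIFamide-related peptide (26.3 ± 0.785 and 38.3 ± 3.19 CPM, 1.46-fold, lost in 2 of 13 settings) and an insulin-like peptide (1.48-fold, lost in 8). The list was lower in females (camera adjusted p = 0.0455; adjusted p = 0.666 with an estimated correlation) and was lost in 7 of 13 settings, among them those without female 1 (0.435), female 2 (0.139), male 2 (0.0676) and male 3 (0.0632). Of 140 neuronal signalling unigenes, 5 were higher in females and 2 in males, as adjusted over the list alone (median -0.03, mean 0.00276, camera adjusted p = 0.686). The 4 named ones were glutamate receptors, a family of ion channels opened by glutamate: glutamate receptor 4-like (2.73-fold) and kainate 5 (2.61-fold) were higher in males, and kainate 2 (1.99-fold) and glutamate receptor 2-like (2.07-fold) in females.

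Of 116 digestive and salivary enzymes, 4 were higher in females and 6 in males (8 and 14 adjusted over the list alone; camera adjusted p = 0.751, median 0.00 and mean -0.03), among them gastric triacylglycerol lipase at 1602 ± 112 and 1037 ± 41.8 CPM, chymotrypsin-2-like (2.41-fold higher in females, lost in 1 of 13 settings) and antichymotrypsin-2, a protease inhibitor (1.62-fold higher in males). Of 40 immune unigenes, Spaetzle, a ligand of the Toll pathway, was 2.1-fold higher in females (lost in 6 of 13 settings) and lysozyme c-1-like, which cleaves bacterial walls, 1.79-fold higher in males (3 and 1 adjusted over the list alone; camera adjusted p = 0.437). By edgeR no unigene passed, over all unigenes or adjusted over the list alone, among 251 of oxidative phosphorylation (camera adjusted p = 0.247), 179 ribosomal proteins (0.686), 90 proteasome subunits (0.536), 36 heat shock proteins (0.686), 75 of DNA replication and mitosis (0.475), 7 of the circadian clock (0.92) and 23 translation elongation factors (0.655). The smallest p in these lists belonged to 60S ribosomal protein L26-like, a mammalian hit (adjusted p = 0.356), proteasome activator complex subunit 4 (0.362), heat shock protein 75 kDa (0.195), centromere-associated protein E (0.145), the clock protein period (0.361) and mitochondrial elongation factor Tu (0.365). At an unadjusted p under 0.05 the counts were 16, 2, 1, 2, 3, 1 and 1, and DESeq2 called 4 of oxidative phosphorylation, 1 of DNA replication and none in the other 5 lists. Many members of these lists had a best hit in a vertebrate, 93 of the ribosomal proteins, 50 of the proteasome subunits, 20 of the heat shock proteins and 11 of the elongation factors, so the counts of 0 cover fewer wasp unigenes than the list sizes. In oxidative phosphorylation, 162 of the 251 had a vertebrate hit; over the other 89 the list was called lower in females with the preset correlation (camera adjusted p = 0.000795; adjusted p = 0.639 with an estimated correlation). So it was over all 251 without female 1 (0.0112) or male 2 (0.0481), while all 6 libraries gave adjusted p = 0.754 with an estimated correlation. Its median was -0.01 and the test pointed down, while its mean was 0.04. The smallest p was that of ATP synthase subunit beta, which makes ATP, at 1045 ± 42.6 and 1295 ± 15.2 CPM (adjusted p = 0.0635). Of 23 tubulins, 2 were higher in females, as adjusted over the list alone (tubulin alpha chain-like 2.08-fold; a tubulin beta chain 1.62-fold, lost in 6 settings; camera adjusted p = 0.655).

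**Figure D2:**
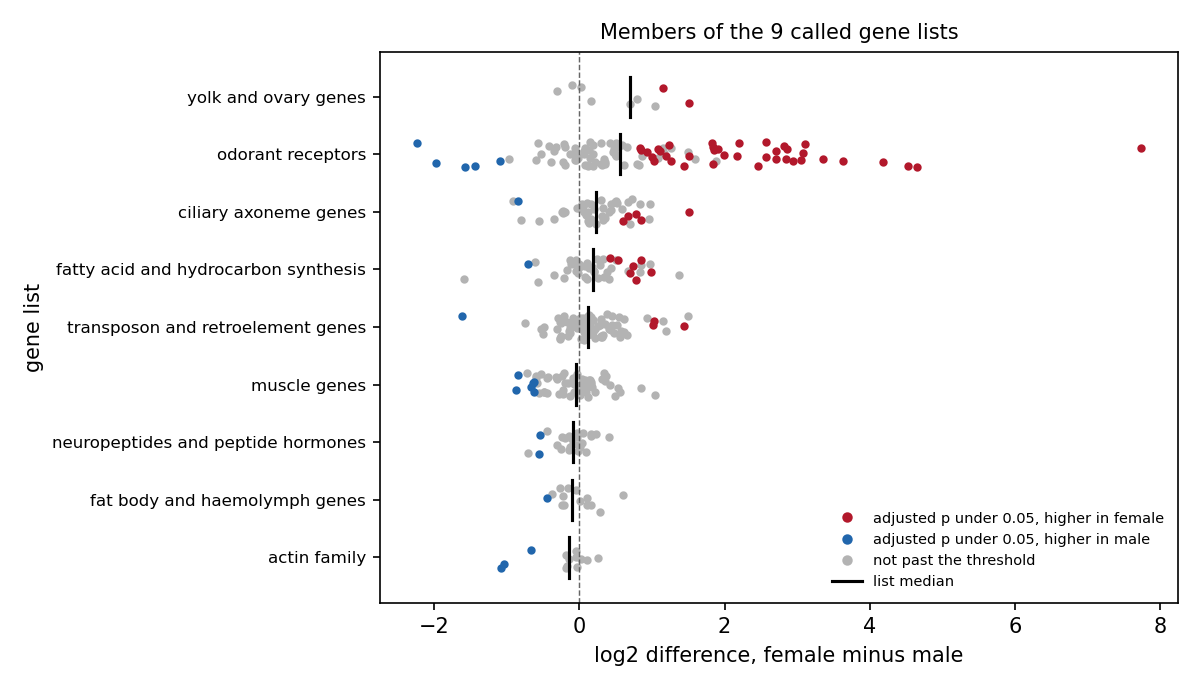
Log2 difference (female minus male) of each unigene in the 9 gene lists that passed the camera test with the preset correlation, with coloured points for adjusted p under 0.05 by edgeR and black bars for list medians. Odorant receptors have 38 points past the test on the female side and 5 on the male side.

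Of 32 lists tested, 9 passed with the preset correlation, 5 higher and 4 lower in females, and 0 passed with an estimated correlation; at an unadjusted p under 0.05 with an estimated correlation, odorant receptors (0.0147), yolk and ovary (0.0247), ciliary axoneme (0.00731) and transposons (0.0109) remained. By fry, 8 lists passed, among them the 5 called higher in females by camera. The other 3 were not called by camera: cytochrome P450 enzymes (adjusted p = 0.0493), sex determination (0.0231) and the yellow and royal jelly family (0.0303). None of the 4 lists called lower in females passed fry (muscle 0.377, neuropeptides 0.353, fat body 0.124, actin 0.0639). Among 4136 tests of annotation terms, 6 passed Fisher's exact test. Olfactory receptor activity held 21 female-higher unigenes of 43 (0.705 expected, adjusted p = 3.55e-23). Detection of chemical stimulus in smell (18 of 42), dendrite membrane (13 of 21) and odorant binding (10 of 17) followed. The pathway of drug metabolism by cytochrome P450 held 6 female-higher unigenes of 57 (adjusted p = 0.0434), and starch and sucrose metabolism 5 male-higher unigenes of 37 (adjusted p = 0.0155). Without vertebrate hits 14 terms passed, without female 1 19, and without female 2 or without male 2 11.

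The candidate reference gene families of the study differed in their spread over the 6 libraries. The design text names GAPDH, actin and heat shock proteins and gives the abbreviations TU, TF and RP, which it does not spell out; tubulin, elongation factor and ribosomal protein stand here as families of the same kind, each by its unigene with the highest mean. Putative elongation factor 1-alpha, which delivers transfer RNA to the ribosome, stood at 1952 ± 76.9 CPM in females and 2030 ± 90.9 in males, with a coefficient of variation of 4.35% and a log2 spread at the 9.4th percentile of unigenes of like level. Ribosomal protein L6 varied by 6.71% (434 ± 16.4 and 464 ± 36.4 CPM) and tubulin alpha-1 by 7.21% (1096 ± 23.3 and 1068 ± 119 CPM). GAPDH 2, a glycolytic enzyme, varied by 15.2% (3669 ± 376 and 4565 ± 483 CPM), with a log2 difference of -0.32 (95% interval -0.56 to -0.07, edgeR adjusted p = 0.238); of the 2 GAPDH unigenes tested none passed over all unigenes and 1 was lower in females adjusted over the list alone, too few for a list test. Heat shock 70 kDa protein cognate 4, a chaperone, varied by 30.2% (1666 ± 360 and 1490 ± 645 CPM), most of it within a sex. Actin (TRINITY_DN25761_c0_g5) varied by 39.3% and was 2.06-fold higher in males (adjusted p = 0.00204), whereas the actin 5C, isoform B unigene varied by 5.84% with a log2 difference of -0.03 (chosen after its values were seen). The geNorm stability value M, lower for steadier genes, was 0.267 for ribosomal protein L6, 0.28 for elongation factor 1-alpha, 0.296 for tubulin alpha-1, 0.325 for GAPDH 2, 0.536 for the heat shock cognate and 0.628 for Actin. M is computed within this set of 6, so each value depends on the other members.

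**Figure D3:**
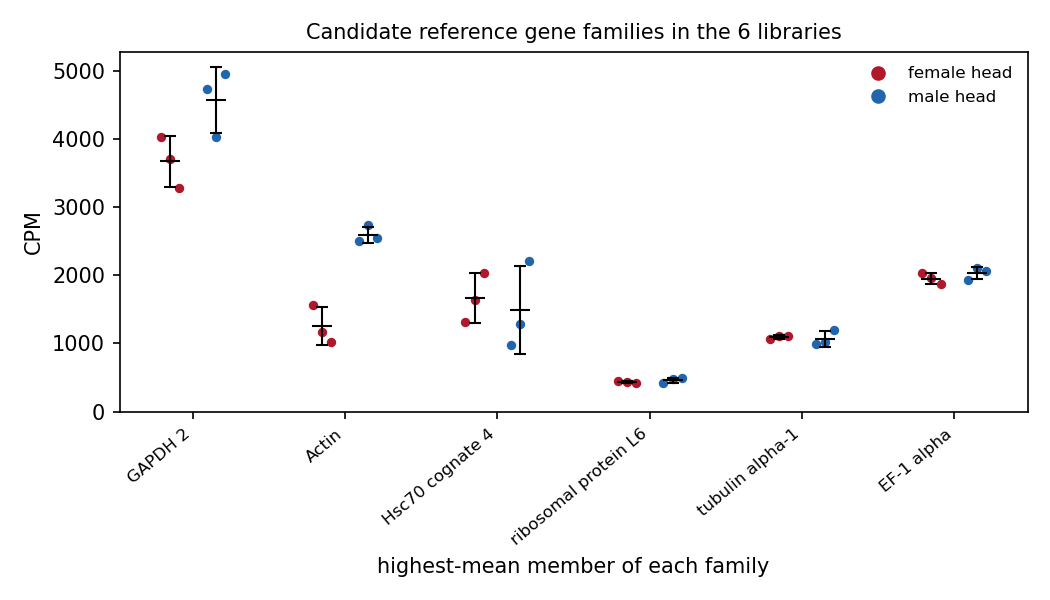
Expression in CPM (linear axis from 0) of the unigene with the highest mean in each of 6 candidate reference families, with points for the 3 female and 3 male head libraries and bars for the mean and SD. Actin stands at 1256 CPM in females and 2592 CPM in males, and elongation factor 1-alpha at 1952 and 2030 CPM.

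The libraries grouped by sex on the first principal component, which held 35.27% of the variance; on the second (22.28%) female 1 lay at 43.6 and females 2 and 3 at -20.5 and -37.3. Correlations of log2 values across genes, which are not independent replicates, ran from 0.975 to 0.985 within a sex and from 0.97 to 0.978 between sexes. By the species of the best database hit, unigenes with a hymenopteran hit held 81.6% ± 0.744 of female counts and 82.9% ± 0.481 of male counts (n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give, adjusted p = 0.525 over 7 kinds of hit). Unigenes with a mammalian hit were 12760 of the 41986 (30.4%), with a median length of 420 bases against 1784 for hymenopteran hits. They held 3.45% ± 0.191 of the counts in females and 3.29% ± 0.215 in males (exact permutation p = 0.4, adjusted p = 0.56). Unigenes with no hit held 13.8% ± 0.945 and 12.6% ± 0.577 (exact permutation p = 0.3, adjusted p = 0.525). Among 5395 tested unigenes with a mammalian hit 1 was higher in females and 3 in males. Among them was a corticosteroid-binding globulin unigene, named for a blood carrier of steroids, at 1.6 ± 0.781 and 25.8 ± 23 CPM (edgeR adjusted p = 0.0234, lost in 4 of 12 settings). Its log2 difference moved from -4.02 to -3.16 without male 2 (adjusted p = 0.0873). A P450 of family 2, subfamily c, was 1.75-fold higher in males (adjusted p = 0.0373, lost in 8 of 12).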

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

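All tests in this part were chosen after the counts on mammalian-hit unigenes had been seen. The comparisons of the report concern the wasp, but unigenes whose best database hit is mammalian held 3.67%, 3.34% and 3.34% of the counts in females 1 to 3 and 3.52%, 3.09% and 3.26% in males 1 to 3, a signal outside the main measurement; the lowest share, 3.09%, lies above the 1.67e-05% that 3 counts make in the shallowest library. Among the abundant ones, cytochrome c oxidase subunit I lay between 1080 and 1280 CPM, serum albumin between 538 and 1020 CPM, thyroglobulin between 169 and 277 CPM and apolipoprotein E between 164 and 199 CPM. Some were uneven between libraries, as BPI fold containing family B, member 9B was at 0.442, 4.01 and 285 CPM in females 1 to 3 and 378, 8.48 and 289 CPM in males 1 to 3, and a second serum albumin unigene was at 230.0 CPM in female 3 and at most 33.7 CPM elsewhere.

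Wasp genes that merely carry mammalian names are argued against as the whole source, provided that each gene gave a single unigene. Of the ribosomal protein names, 72.2% (57 of 79) were held both by a hymenopteran-hit and by a mammalian-hit unigene. A wasp gene split into several unigenes could hold hits of both kinds, and the shared names do not separate that case. Serum albumin (538 to 1020 CPM), thyroglobulin (169 to 277 CPM) and apolipoprotein E (164 to 199 CPM) are vertebrate proteins. Their presence argues against split wasp genes for these unigenes. A single mammalian source mixed in the same proportions into every library stays open for the unigenes as a set; it was first read as argued against, and the bound was changed after the value of 16.9% had been seen. Of the 5958 unigenes with at least 50 counts, 16.9% (1007) departed from a constant share (chi-square over the 6 libraries, adjusted p under 0.05; median per degree of freedom 1.43, with 0.87 expected and 4.84 for hymenopteran hits), a test that covers counting error and not noise of library preparation. That noise was not measured. It is a poor account of the most uneven members, BPI member 9B and the second albumin. So it is of the 72 of the 1007 over 5 times their median in female 3 (at most 4 in any other library). Paired mitochondrial unigenes, chosen after their values were seen, also shifted. Cytochrome c oxidase subunit I stood at 1280 and 334 CPM in female 1 and at 1200 and 384 CPM in male 3. Subunit III stood at 1070 and 259 CPM in female 1 and at 1050 and 322 CPM in male 3. For these unigenes the values argue against the same proportions in every library, unless noise of preparation moved them. RNA of a mammal from outside the wasps, through handling, reagents or other libraries of a run, may be the source, its entry is not identified by these data, and no biological explanation was tested.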

How the results depend on the processing

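The setting without vertebrate hits and the scaling to hymenopteran counts were chosen after seeing the data. No result reversed by its test under the alternatives run. Against 593 unigenes called, 358 higher in females and 235 in males, leaving out a library gave 357 to 688 calls, 210 to 382 higher in females and 144 to 306 in males, the lowest totals without female 2 (358) and male 2 (357); fewer samples enter those fits. In each of the 6 such fits 305 of the 593 were called. Asking for a log2 difference of at least 1 left 271, 164 and 107 by construction. DESeq2's Wald test called 359 higher in males (817 in all); the cause was not tested, though its simulated false calls were also more frequent. Scaling to hymenopteran counts called 654, 458 higher in females and 196 in males, with a median shift over all unigenes of 0.07. No called unigene changed sign in any alternative that was compared with the 593. Lists called numbered 9, and 7 to 11 without a library. With an estimated correlation there were 0, over all unigenes and without vertebrate hits (the latter chosen after seeing the data). The estimates of the axoneme (-0.00723), transposon (-0.00577) and fat body (-0.0148) lists lay below the preset value of 0.01. The camera p of the axoneme list still rose from 3.08e-05 to 0.00731. A higher correlation among members is thus not why these lists lost the call. With an estimated correlation camera also takes its p from the few residual degrees of freedom of the 6 libraries, which raises p for a like statistic. How much of the loss in the other lists came from this or from correlation was not tested. Over 416 results of single lists, 25 lost the call and 9 gained it; over 1163 of named unigenes, 75 lost it and 6 gained it. Enriched terms numbered 6, with 4 to 19 without a library and 14 without vertebrate hits; the cause was not tested. The mean geNorm M was 0.389, with 0.344 to 0.428 without a library and 0.48 with the second-highest member of each family, a set that holds other genes. The labels number libraries alike in both sexes. Same-numbered libraries deviated with correlations of -0.0193, -0.0699 and -0.00904 across unigenes, so no broad pairing by number was seen. A pairing that touches fewer unigenes is not excluded. Heat shock protein 83-like and heat shock 70 kDa protein cognate 4 were highest in female 3 and male 3. So were most other heat shock unigenes of at least 50 CPM without a vertebrate hit. Cognate 3 was at 401 CPM in female 3 and 457 CPM in male 3, the highest of each sex. Heat shock protein 68-like and heat shock protein 75 kDa were not highest there. A pattern shared by libraries of number 3 was thus seen in this family. A replicate block gave 576 calls. Low counts kept 20790 of 41986 unigenes outside the test. Tested were 9457 of 10991 with a hymenopteran hit, 5395 of 12760 with a mammalian hit and 6071 of 17680 with no hit. The splits of 6 libraries into 3 and 3 are 10, too few for a share under 0.05: the split by sex called 593 unigenes, 9 lists and 6 terms, and the highest of the other splits 9, 5 and 2.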

Other observations

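Every test in this part was chosen after the result it bears on had been seen. Among the 593 unigenes that differed between the sexes, 129 had no database hit, 71 higher in females and 58 in males. Of these, TRINITY_DN26069_c0_g3 stood at 200.3 ± 13.3 CPM in females and 1.44 ± 0.315 in males, and TRINITY_DN4114_c0_g1 at 140.4 ± 13.6 and 0.546 ± 0.211 CPM (n = 3 libraries per sex). The assembly cluster DN26448 held the odorant receptors 13a-like and 22c-like, olfactory receptor 9 and a glutathione S-transferase, a conjugating enzyme, all higher in females. Heat shock protein 83-like, a chaperone, varied by 49.8% over the 6 libraries, with 1636 CPM in female 3 and 2185 CPM in male 3 against 591 to 1019 CPM in the others, and heat shock 70 kDa protein cognate 4 was also highest in female 3 (2037 CPM) and male 3 (2213 CPM).

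Odorant receptor unigenes were higher in female heads as a list, by a median log2 difference of 0.56, a call made with the preset correlation and lost with an estimated correlation (adjusted p = 0.157). The explanation of 1 gene counted as several unigenes is argued against for unigenes that share an assembly cluster. With 1 unigene per cluster (62 clusters, 19 higher in females and 3 in males) the camera p with the preset correlation was 1.14e-10. Pieces of 1 gene that fell in different clusters would still count separately, so the explanation stays open for them. Library scaling cancels in a ratio within a library. A larger share of smelling tissue with an unchanged mix of cells would move the receptors together with Orco. Each is argued against as the whole cause. In 76 of 103 receptor unigenes the log ratio to Orco within a library differed between the sexes (limma, adjusted p under 0.05, 24 above and 52 below). Against such a share of tissue, 5 receptors were also higher in males. Odorant-binding proteins went both ways (4 and 5 of 13 without vertebrate hits). All 103 ratios share Orco as their denominator. They cannot tell more smelling cells of some kinds from a change of expression within cells, so a changed mix of cells stays open. An earlier form of this test, on fitted differences, gave 80. An earlier test of scaling on random lists was dropped because it could not decide. A part of the difference could still come from more smelling tissue. Both ionotropic receptors (2.57-fold and 2.11-fold) were higher in females by about as much as Orco (2.35-fold). Intraflagellar transport protein 52 (2.86-fold) was too, but it had the smallest p of the axoneme list. That list had a median of 1.17-fold, with 5 of 47 higher in females and 1 in males. The axoneme list was called higher and the muscle and actin lists lower, each with the preset correlation and not with an estimated correlation. That female and male heads differ in which receptors they express is then a hypothesis, found and tested on the same 6 libraries. Quantitative PCR of the named receptors relative to Orco could test whether the ratios recur in new animals. It could not tell a changed mix of smelling cells from a change of expression within cells.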
